A study of Mus musculus with 2 samples.

How the data were processed

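H3K36me3 ChIP-seq was run on kidney tissue of mouse embryos (strain B6NTac;B6NCrl/Lap) at 14.5 days, in 2 biological replicates from pooled embryos of both sexes, per the labels. Replicate 1 combined 2 technical replicates and replicate 2 had 1. The labels name separate biological replicates but not the embryos in each pool, so the spread between them may hold technical as well as biological differences.

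The deposited files are peak lists in narrowPeak layout. Per the text files deposited with the samples, peaks were called on each replicate alone, on both replicates together (the pooled list), and a replicated list was derived from these 3, all in mm10. The aligner, the peak caller, its threshold and the rule for keeping a replicated peak are not given in the sources used here. Each peak carries a fold enrichment over background, a linear ratio computed by the authors. Whether that background is a control library or a local level is not given in the sources used here. It also carries −log10 p and −log10 q values set by the authors' caller. These are the authors' own values per peak and were used to describe, rank, filter and match peaks within a list. Between the replicate lists they were compared only as a ratio of X to autosomes formed within each list. The lowest −log10 p was 2.06 in both replicate lists, so a region without a peak is below that threshold and not shown to lack the mark. The lists hold no read counts, so depth is unknown. The number of peaks and covered bases reflects depth and enrichment together, and a difference in coverage between replicates can come from either.

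Peaks on chromosomes 1 to 19, X and Y were used. All intervals fitted the chromosome lengths of GRCm38, the same assembly as mm10, and genes came from GENCODE release M21 on that assembly. Assembled bases are those that are not N in the reference sequence. Gene bodies ran from annotated start to end, an exon was any base exonic in any transcript of the gene, and coordinates are 1-based. Gene results used protein-coding genes of at least 1 kb, the longest where a symbol occurs more than once, 21196 in all. For each gene the percent of the body covered by merged peaks was computed per replicate, and a gene with at least 10% in both replicates was called marked. Of these genes 4540 overlap another protein-coding gene, and a peak in shared sequence counts for both.

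Gene lists for kidney cell types, other cell types, cellular machinery and gene families, the rule for naming genes, the tests and the alternatives were fixed before the data were examined. The text names 16 genes fixed beforehand, genes among the 10 of at least 5 kb with the highest coverage times enrichment, up to 2 highest and 2 lowest members of each list, whole lists with 5 or fewer marked members, Hox genes, genes under the 5 widest replicated regions, and genes among the 5 of at least 5 kb with the largest replicate difference each way. Other genes were chosen after their values were seen: Hjurp, the genes beside marked list members, the non-coding genes, the genes on unplaced contigs, and the zinc finger genes under the strongest peaks. The number of marked members of each list was compared with 10000 random lists drawn from genes in the same decile of gene length, in a two-sided permutation test with Benjamini-Hochberg adjustment over 29 lists. Genes are not independent replicates, so these p-values say whether a list stands apart in these 2 libraries. Listed genes under 1 kb (Hba-a1, Hba-a2, Ahsp, Ifna1 and Ifnb1), non-coding ones (H19, Meg3 and Kcnq1ot1) and the older symbols Whsc1 and Whsc1l1 were not measured. Lists set by a symbol pattern, such as ribosomal protein, olfactory and histone genes, took in only genes of at least 1 kb. Shorter genes that fit a pattern were left out of the counts.

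Replicate peaks counted as shared with at least 50% of their length inside peaks of the other replicate, and 100 random placements within the same chromosome gave the level by chance. Shares of peaks have Wilson 95% intervals. The body profile used 20 bins and 5 kb flanks in genes of at least 5 kb. Correlations over 19 autosomes have permutation p-values from 100000 resamples. Covered-base counts were checked against a base-by-base count (0 of 2050 values differed). The list test was tested on simulated data with 21196 genes and lists of 20 members, at an unadjusted p of 0.05. It called 2 of 100 unchanged lists, 92 of 100 lists marked 2.5 times as often and 79 of 100 lists marked 0.1 times as often. Marks were simulated independently for each gene, and members were drawn without regard to position. These rates may therefore not hold for lists of neighbouring or overlapping genes, such as the Hox lists. The alternatives were stricter peak thresholds, equal peak numbers, merging peaks within 1 kb, each replicate alone, the replicated list, other definitions of a marked gene, other overlap rules and other gene sets. Work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.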

Results

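Trimethylation of histone H3 at lysine 36 (H3K36me3), a chromatin mark laid down over the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing in whole kidneys of mouse embryos at 14.5 days of gestation. At this age the kidney holds nephron progenitors, a branching ureteric bud, early nephrons, stroma, vessels and blood cells together. There was 1 group of 2 biological replicates, each made from pooled male and female embryos, and no second condition. The measurements were peak lists in mm10 coordinates. The list of replicate 1 held 148458 peaks covering 66.3 Mb, or 2.503% of the assembled bases. That of replicate 2 held 197511 peaks covering 128.5 Mb, or 4.85%. The lists hold no read counts, so the sequencing depth behind each peak is unknown.

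The peaks lay almost entirely inside protein-coding genes. Bodies of these genes held 95.5% ± 0.44 (SD, n = 2) of the covered bases and 39.3% of the genome, a 2.43 ± 0.011-fold excess. Exons of protein-coding genes made up 24.7% ± 2.69 of the covered bases against 3.63% of the genome, and introns 70.8% ± 2.25 against 35.6%. Sequence more than 5 kb from every annotated gene, 43.2% of the genome, held 0.143% ± 0.014 of the covered bases. Other annotated genes, counted only where they lie outside protein-coding bodies, held 0.742% ± 0.107. Each of these differences from the genome share was larger than the spread between the replicates.

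Coverage rose along the gene toward its 3' end. Over 5856 marked genes of at least 5 kb, peaks covered 17.3% ± 8.01 (SD, n = 2) of the bases in the first 5 of 20 equal bins of the body and 59.4% ± 17.6 in the last 5. The ratio of the last to the first 5 bins was 4.03 in replicate 1 and 3.13 in replicate 2, with a mean of 3.58 ± 0.639. The first bin after the transcription start was covered to 2.26% and the bin with the highest coverage, bin 18, to 61.5%. Peaks ran past the annotated end, covering 42.2% ± 16.1 of the first downstream kb. Exons of marked genes were covered to 55.5% ± 15.8 and their introns to 35.7% ± 14.6. The ratio of exon to intron coverage was above 1 in each replicate, at 1.75 and 1.45. Exon and intron bases were pooled without matching on position, so the rise toward the 3' end may contribute to this ratio.

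**Figure D1:**
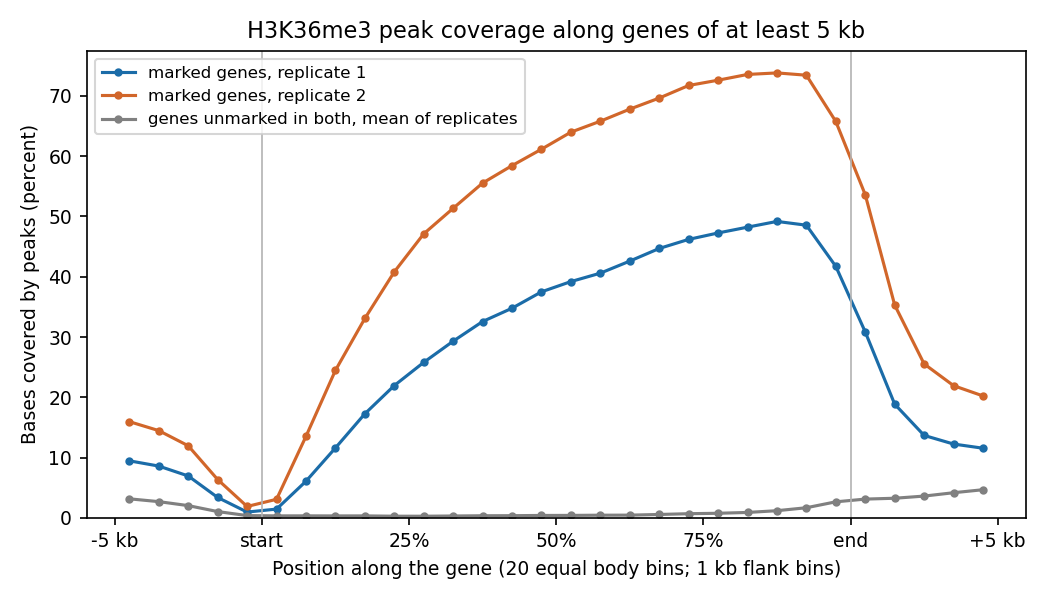
Percent of bases covered by H3K36me3 peaks (vertical axis) along genes of at least 5 kb, in 20 equal bins from transcription start to end and in 1 kb bins of the 5 kb flanks (horizontal axis). Lines show the 5856 marked genes in replicate 1 and in replicate 2 and, in grey, the mean over replicates of genes unmarked in both; coverage of marked genes climbs from 2.26% in the first bin to 61.5% in bin 18 as a mean over replicates.

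Of 21196 protein-coding genes of at least 1 kb, 6471 (30.5%) carried the mark over at least 10% of their body in both replicates and are called marked here. No base of 9432 genes was covered in either replicate, and 1200 genes were covered to at least 50% in both. The genes with the highest coverage and enrichment together included Fasn, the cytosolic fatty acid synthase (chr11:120805846-120824547), covered to 86.8% ± 2.26 (SD, n = 2). They also included Gigyf1 (chr5:137518548-137527935) at 94.3% ± 5.43, Hsp90ab1, a constitutive chaperone, at 70.4% in replicate 1 and 80.8% in replicate 2, and Atp5b, a subunit of mitochondrial ATP synthase, at 74.2% and 85.2%. The 5 widest regions of the replicated list lay over Dync1h1, the heavy chain of cytoplasmic dynein (chr12:110615539-110644936, 29.4 kb), Smarca4, a chromatin remodelling ATPase (chr9:21658324-21681494, 23.2 kb), Sf3b3, a spliceosome subunit (chr8:110809181-110832295, 23.1 kb), Notch1, a receptor in cell fate choice (chr2:26459458-26482170, 22.7 kb) and Zmiz1 (chr14:25642297-25664855, 22.6 kb). These widths are those of peaks called on both replicates together, whose intervals the replicated list keeps. The widest single peak was 9543 bp in replicate 1 and 29500 bp in replicate 2. Regions this wide were therefore not single peaks in replicate 1.

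Genes of the basic machinery of dividing cells were marked far more often than genes of the same length. All 22 of the genes for the replicative helicase and the cell cycle and all 22 splicing factors were marked, against 7.92 and 7.83 in random lists matched on gene length. Top2a, a topoisomerase of dividing cells, was covered to 85.1% ± 9.44 (SD, n = 2) and Mcm2, a helicase subunit, to 80.2% ± 11.8. The least covered member, Pcna, the sliding clamp of replication, was at 43.0% ± 13.5. Among splicing factors, Prpf8 reached 87.9% ± 4.35 and Sf3a1 87.7% ± 10.6. Of 82 ribosomal protein genes 69 were marked against 16.5 expected, led by Rps3 at 81.1% ± 2.18 and Rps5 at 78.4% ± 7.32. Rpl10l and Rpl39l, retrogene copies in that family, had no covered base. Marks lay on 31 of 36 subunits of mitochondrial complex I (11.02 expected; Ndufa10 72.8% ± 17.8, Ndufs1 63.5% ± 15.9) and 31 of 39 proteasome subunits (12.9 expected; Psmc1 76.2% ± 12.2, Psmc4 74.3% ± 17.2). Psma8 and Psmb11, proteasome subunits known from testis and thymus, had no covered base.

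Genes linked to H3K36 methylation and genes named Zfp, a set defined by symbol, were also marked more often than genes of the same length. Of 23 genes listed as writers, erasers and readers of H3K36 methylation 19 were marked against 7.11 expected. Kdm4a, a demethylase, was covered to 74.0% in replicate 1 and 90.9% in replicate 2 and Brpf1, a reader, to 73.5% ± 10.7 (SD, n = 2), while Setmar stayed at 7.31% ± 3.19. Of 391 genes named Zfp 206 were marked against 140.8 expected, with Zfp869 at 89.3% ± 9.03 and Zfp606 at 81.8% ± 8.47, while Zfp114 and Zfp185 had no covered base. For each of these 7 lists the permutation p was 0.0002, the smallest that 10000 random lists can give in a two-sided test, and the adjusted p over 29 lists was 0.00064 (Benjamini-Hochberg). At a threshold of 50% of the body the complex I list was marked 0.845 times as often as the random lists (adjusted permutation p = 1) and the Zfp list 1.15 times (adjusted permutation p = 1), so both calls depended on that threshold.

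**Figure D2:**
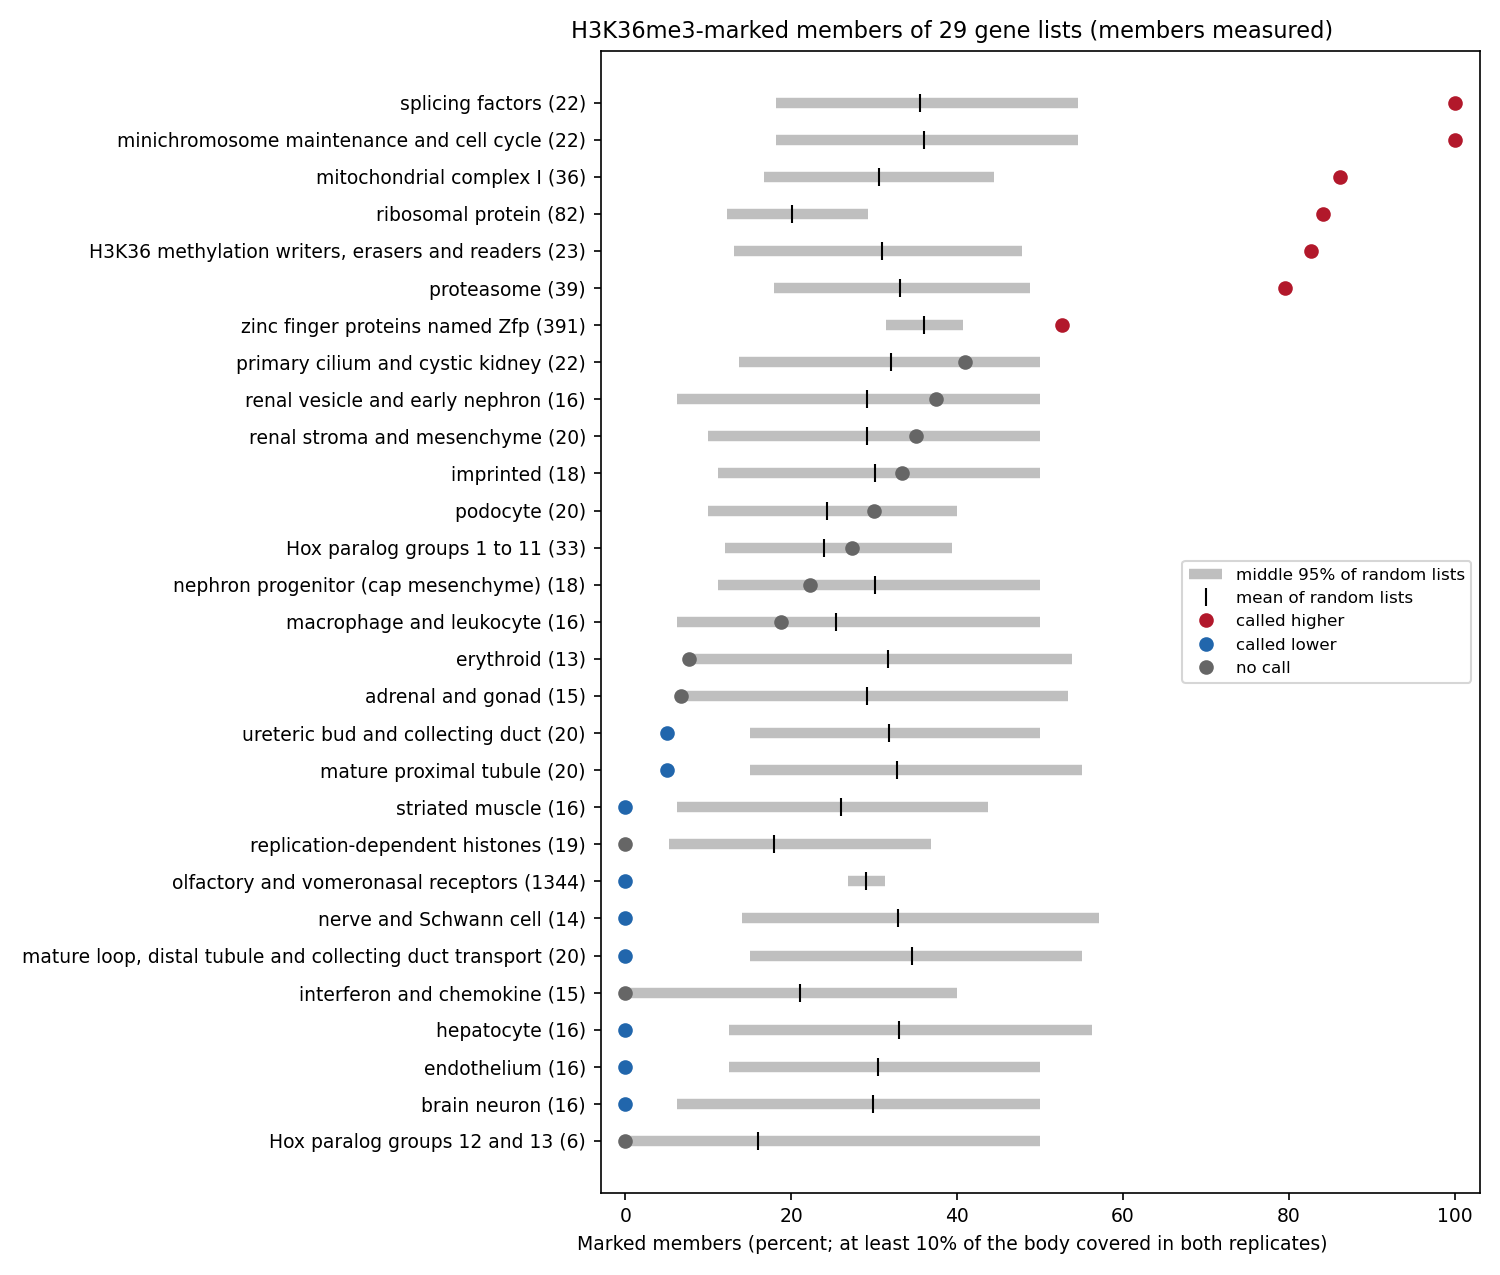
Percent of measured members that were marked (horizontal axis; at least 10% of the gene body covered in both replicates) for 29 gene lists, with the number of measured members in brackets. Grey bars show the middle 95% and black ticks the mean of 10000 random lists matched on gene length. Points are coloured by the call at an adjusted p of 0.05, with 7 lists called higher than their random lists and 9 called lower.

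Lists of cell types that build the embryonic kidney were marked in part. In the nephron progenitor list 4 of 18 members were marked (5.42 expected, adjusted permutation p = 0.796). These were Pax2 (chr19:44756045-44837871) at 50.9% ± 24.8 (SD, n = 2), Wt1 (chr2:105126529-105173616) at 39.2% ± 27.3, Sall1 at 28.6% ± 8.19, all transcription factors, and Gdnf, the signal that draws the ureteric bud, at 24.0% ± 18.6. Six2, the regulator of progenitor self-renewal, had 0% in replicate 1 and 6.38% in replicate 2, and Cited1 had no covered base. In replicate 2 alone 8 members of this list passed 10%, and without replicate 1 the ratio to expected went from 0.738 to 1.11, with no call either way. In the stroma and mesenchyme list 7 of 20 were marked (5.84 expected, adjusted permutation p = 0.796), with Col1a1 at 56.5% ± 27.0, Col1a2 at 39.7% ± 32.8 and Pdgfra at 14.3% in replicate 1 and 58.2% in replicate 2, while Foxd1, the stromal progenitor factor, stood at 0% and 5.88%. In replicate 2 alone 12 of its members passed. The early nephron list had 6 of 16 (4.66 expected, adjusted permutation p = 0.796), with Ccnd1, a cyclin, at 58.5% ± 18.5 and Jag1, a Notch ligand, at 49.3% ± 17.3. In the podocyte list 6 of 20 were marked (4.87 expected, adjusted permutation p = 0.796), among them Vegfa at 57.7% ± 10.2 and Foxc2 at 41.7% ± 22.2, and Nphs1, the slit diaphragm protein nephrin, had no covered base. Wt1 stands in both the progenitor and the podocyte list.

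The ureteric bud list was marked less often than expected, with 1 of 20 members against 6.36 (adjusted permutation p = 0.0155). The marked member was Hnf1b (chr11:83850063-83905819), a transcription factor that the early nephron list also holds, at 20.4% ± 8.58 (SD, n = 2). Ret, the receptor for Gdnf, was covered to 0% in replicate 1 and 1.05% in replicate 2. In replicate 2 alone 6 of its members passed 10%, and without replicate 1 the list was no longer called (adjusted permutation p = 0.441). Endothelial genes gave 0 of 16 against 4.86 expected (adjusted permutation p = 0.0133), with Kdr, a receptor for Vegfa, at 1.51% ± 1.32. That call was also lost without replicate 1 (adjusted permutation p = 0.116), where Egfl7, Ets1 and Eng passed 10% at 22.4%, 15.1% and 12.7%.

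Genes of tubules that are not yet mature were hardly covered. Of 20 genes of the mature proximal tubule 17 had no covered base and 1, Slc5a2, a glucose transporter, was marked (6.54 expected, adjusted permutation p = 0.0127). Slc5a2 overlaps another marked gene, BC017158. Aqp1, Slc34a1, Cubn and 14 other members had 0% in both replicates. Of 20 transport genes of the mature loop, distal tubule and collecting duct 0 were marked (6.91 expected, adjusted permutation p = 0.00064), and Umod, Slc12a1 and Aqp2 had no covered base. The proximal tubule call held in 13 of 16 alternatives and the loop and distal call in 14. Both were lost with −log10 q of at least 5 and at 50% of the body. The cilium and cystic kidney list had 9 of 22 marked (7.03 expected, adjusted permutation p = 0.655). Pkd2, a channel mutated in polycystic disease, was covered to 54.8% ± 20.5 (SD, n = 2) and Ift172 to 52.1% ± 18.3, while Pkhd1 stood at 0% and 0.193%. Without replicate 1, 16 of these 22 passed and the list was called higher (adjusted permutation p = 0.0279).

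**Figure D3:**
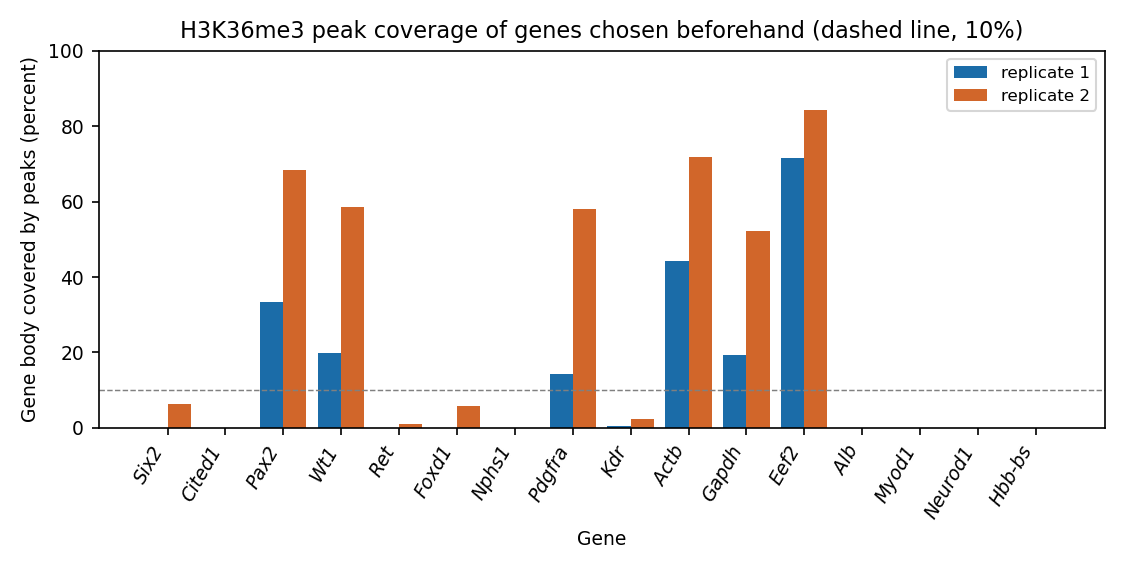
Percent of the gene body covered by H3K36me3 peaks (vertical axis) in replicate 1 and replicate 2 for 16 genes (horizontal axis) fixed before the data were examined. Pax2, Wt1, Pdgfra, Actb, Gapdh and Eef2 pass the dashed 10% line in both replicates, and Cited1, Nphs1, Alb, Myod1, Neurod1 and Hbb-bs have no covered base.

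Lists for liver, brain, nerve and muscle cells had no marked member. Hepatocyte genes gave 0 of 16 against 5.28 expected (adjusted permutation p = 0.00464), with Alb at 0%. Brain neuron genes gave 0 of 16 (4.77 expected, adjusted permutation p = 0.0133), with Neurod1 at 0%, nerve and Schwann cell genes 0 of 14 (4.61 expected, adjusted permutation p = 0.0133) and striated muscle genes 0 of 16 (4.17 expected, adjusted permutation p = 0.0214), with Myod1 at 0%. The hepatocyte call held in 13 of 16 alternatives, the nerve call in 12, and the brain neuron and muscle calls in 11. None of 1344 olfactory and vomeronasal receptor genes had a covered base, against 390.2 marked in random lists (adjusted permutation p = 0.00064). Blood cell lists were not called. Erythroid genes had 1 of 13 marked (4.11 expected, adjusted permutation p = 0.132), Tfrc, the transferrin receptor, at 54.7% ± 22.4 (SD, n = 2), while Hbb-bs, an adult beta globin, had no covered base. Macrophage and leukocyte genes had 3 of 16 marked (4.07 expected, adjusted permutation p = 0.800). These were Cd68 at 71.2% ± 40.7, Fcer1g at 17.4% ± 6.62 and Cx3cr1 at 15.8% ± 3.91, each with another marked gene within 1 kb, and Ptprc, Tyrobp and C1qa had no covered base. Adrenal and gonad genes had 1 of 15, Star, at 33.4% ± 20.0 and likewise beside a marked gene, Ash2l (4.37 expected, adjusted permutation p = 0.109). Replication-dependent histone genes of at least 1 kb, 0 of 19 (3.40 expected, adjusted permutation p = 0.0672), were not called. Nor were interferon and chemokine genes, 0 of 15 (3.16 expected, adjusted permutation p = 0.0834). But the histone list was called lower in 3 of 16 alternatives and the interferon list in 5, among them without replicate 1 (adjusted permutation p = 0.0251). In replicate 2 alone 2 members each of the erythroid and the adrenal and gonad list passed, and the latter was called lower in 2 of 16 alternatives. Imprinted genes had 6 of 18 (5.42 expected, adjusted permutation p = 0.946), with Igf2r at 49.0% ± 23.8 and Peg3 at 39.2% ± 25.2.

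Hox genes, the transcription factors that set position along the body axis, were marked within paralog groups 2 to 9. Of 33 genes of paralog groups 1 to 11, 9 were marked (7.89 expected, adjusted permutation p = 0.800), and of 6 genes of groups 12 and 13, 0 (0.957 expected, adjusted permutation p = 0.796), which is too few expected for a call. In replicate 2 alone 14 of the 33 passed. Hoxa5 (chr6:52201754-52204587) was covered to 66.4% ± 16.2 (SD, n = 2), Hoxb3 to 22.3% in replicate 1 and 57.7% in replicate 2, and Hoxb5 to 17.6% and 57.6%. The others that passed in both were Hoxa3, Hoxa6, Hoxa9, Hoxb2, Hoxb4 and Hoxd4, at 10.7% to 20.7% in replicate 1 and 19.2% to 38.1% in replicate 2. No gene of the Hoxc cluster passed, the highest being Hoxc9 at 0% and 8.05%. Hoxd11 and Hoxa11, needed for kidney outgrowth, stood at 5.92% and 4.14% and at 0% and 5.13%.

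**Figure D4:**
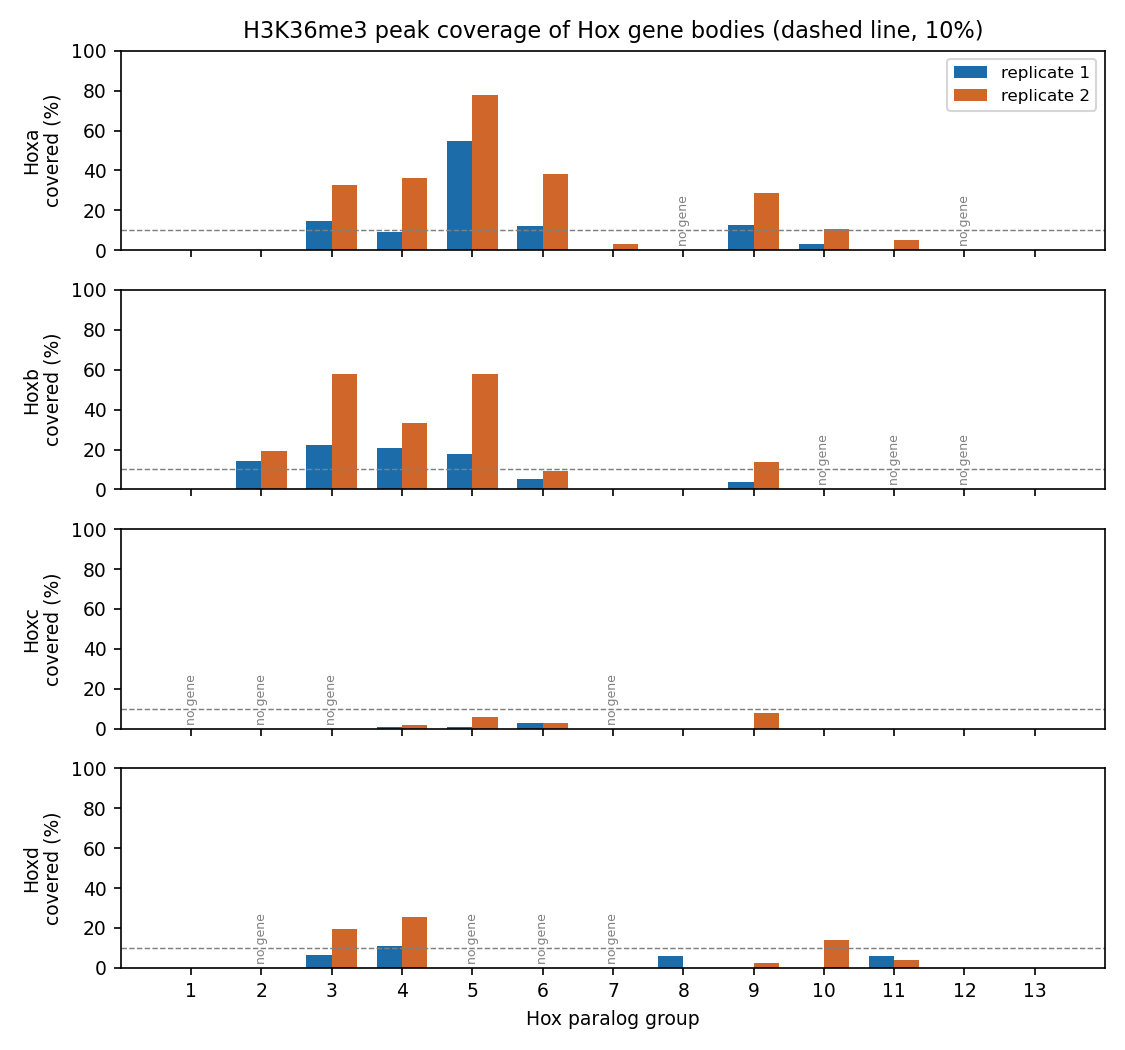
Percent of each Hox gene body covered by H3K36me3 peaks (vertical axis) by paralog group (horizontal axis), 1 panel per cluster, with bars for replicate 1 and replicate 2 and a dashed line at 10%. Coverage is highest at Hoxa5, at 54.9% and 77.8%, and is 0 in all genes of groups 12 and 13.

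Coverage differed by chromosome with gene content. Chromosome 11 was covered most, to 6.78% ± 2.78 (SD, n = 2) of its assembled bases, and chromosome 3 least of the autosomes, to 2.57% ± 1.26. Across the 19 autosomes, the mean covered percent rose with the percent of the chromosome inside protein-coding genes (Pearson r = 0.820, Spearman rho = 0.840, permutation p = 1e-05 for each, the smallest that 100000 resamples can give; adjusted p over both = 1e-05). Without the 2 chromosomes farthest from the median gene content r was 0.800. Chromosomes are not independent replicates, so these p-values only describe the 19 autosomes in these libraries. Since 95.5% of the covered bases lay inside protein-coding bodies, the rise largely follows from where the peaks lie and is no separate evidence. The X chromosome was covered to 0.250% in replicate 1 and 1.101% in replicate 2, a ratio of 4.40 where the autosomes ran from 1.80 to 2.08. Of 877 X genes 53 were marked against 249.4 in random lists matched on length (permutation p = 0.0002, the smallest possible), and in replicate 2 alone 178 against 338.4. Of the 5 genes of at least 5 kb with the largest excess in replicate 2, 3 are on X. These are Med12, a Mediator subunit, at 21.03% in replicate 1 and 74.1% in replicate 2, Zrsr2 at 7.25% and 57.1% and Htatsf1 at 5.29% and 54.4%.

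**Figure D5:**
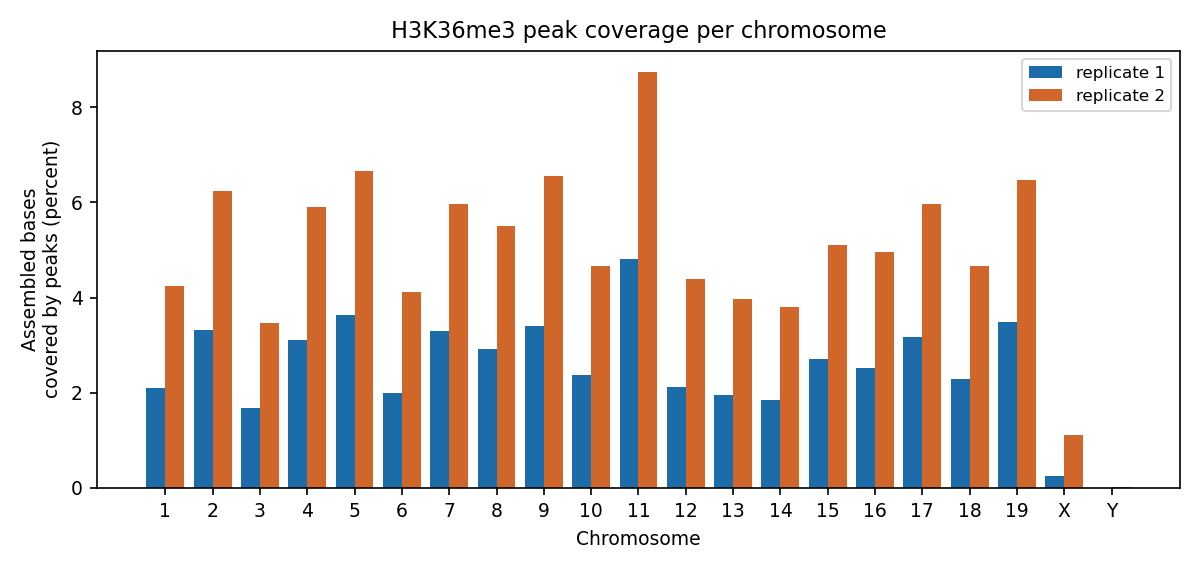
Percent of assembled bases covered by H3K36me3 peaks (vertical axis) per chromosome (horizontal axis), with bars for replicate 1 and replicate 2. Chromosome 11 is highest in both at 4.81% and 8.75%, and X stands at 0.250% and 1.101%.

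Genes marked in replicate 1 were nearly all marked in replicate 2, which marked more genes and covered them more broadly. Across the 21196 genes the covered percent of both replicates correlated with a Spearman rho of 0.952 and a Pearson r of 0.950, a description across genes, which are not independent replicates. Both coefficients include 9432 genes with no covered base in either replicate. The correlation over covered genes alone is not given here. Replicate 1 passed 10% in 6489 genes and replicate 2 in 8673, with 18 genes passing in replicate 1 alone and 2202 in replicate 2 alone. In 6435 of the 6471 genes marked in both, coverage was higher in replicate 2, and the median over these genes was 30.2% in replicate 1 and 54.0% in replicate 2. Among genes of at least 5 kb, Vash2 and Col6a1 showed the largest autosomal gaps, at 25.9% against 73.6% and 8.42% against 55.7%. In the other direction, coverage was higher in replicate 1 at Zdhhc24, with 10.2% against 0%, and at Tmem177, with 17.8% against 8.78%. Covered bases were 1.94 times and peaks 1.33 times as many in replicate 2.

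By the share of a peak lying inside the other list, peaks of replicate 1 were mostly found again and those of replicate 2 mostly were not. Of the replicate 1 peaks 84.5% (95% Wilson interval 84.3 to 84.7) had at least 50% of their length inside replicate 2 peaks, 14.9 times the 5.66% of random placements on the same chromosome. Of the replicate 2 peaks 29.1% (28.9 to 29.3) lay inside replicate 1 peaks, 10.6 times the random 2.75%. When at least 50% of both peaks had to be shared, the shares were 24.1% and 18.1%. These intervals cover counting error only. The Jaccard index by bases was 0.424 against 0.0193 for random placement. By bases, 87.6% of replicate 1 and 45.2% of replicate 2 lay in peaks of the other list. Replicate 1 covered 66.3 Mb and replicate 2 128.5 Mb, so the bases of replicate 2 could not all lie in replicate 1 peaks. List size thus limits the replicate 2 share, and its low value alone does not show poor reproducibility. Since both lists lie in the same genes, placement inside genes marked in replicate 2 is the closer comparison, and there 87.4% of replicate 1 peaks were found again against 38.0% at random, 2.30 times as many. The 104712 replicate 2 peaks that shared no base with replicate 1 (53.0%) were narrow, with a median of 270 bp and a median fold enrichment of 3.41, against 664 bp and 4.96 for those found again. Of the 70.5 Mb covered in replicate 2 only, 64.0% lay in genes marked in both replicates.

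The authors' replicated list kept 65.3% of the peaks called on both replicates together and 86.7% of their bases. Every one of its 108035 peaks on the assembled chromosomes had the interval of such a pooled peak. Of these kept peaks 80.7% shared a base with peaks of both replicates, 81.5% with replicate 1 and 99.2% with replicate 2. Peaks that were kept had a median width of 587 bp and a median fold enrichment of 3.91, and those that were dropped 236 bp and 2.88.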

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

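These values were read off after the other results and no test of them was planned. Peaks on sequence contigs that the assembly does not place on a chromosome stood outside every comparison. Replicate 1 held 5 and replicate 2 held 13. In replicate 1 all lay on contigs assigned to chromosome 4. In replicate 2 another 5 lay on a contig assigned to X, over Vamp7, a vesicle fusion protein, and Tmlhe, an enzyme of carnitine synthesis, where replicate 1 had no peak. No biological explanation was tested.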

How the results depend on the processing

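Random placement inside genes and the restriction to autosomes were chosen after seeing the data, and the other alternatives before. The excess in protein-coding bodies stayed above 2-fold: 2.45 with −log10 q of at least 5, 2.44 with peaks at or above the median enrichment, 2.09 over all annotated genes and 2.22 with bodies extended by 5 kb (2.42 to 2.44 with 1 replicate left out). The ratio of the last to the first bins was 4.67 with −log10 q of at least 5 and 2.77 in genes of at least 20 kb (3.26 to 4.03 with 1 replicate left out). The exon to intron ratio (1.53 to 1.79) and the correlation with gene content (rho 0.819 to 0.849) kept their direction in every alternative run. Marked genes numbered 3366 with −log10 q of at least 5, 3934 at 25% and 1200 at 50% of the body, against 6471 (6489 to 8673 with 1 replicate left out, and 6418 on autosomes).

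Replicate overlap depended on its definition. For −log10 q of at least 2, −log10 q of at least 5, median enrichment, equal peak numbers and merging within 1 kb in that order, the Jaccard index was 0.408, 0.270, 0.389, 0.451 and 0.535. The share of replicate 1 peaks found again was 86.4%, 93.4%, 83.4%, 80.4% and 78.9%, and that of replicate 2 peaks 27.2%, 15.03%, 27.5%, 35.2% and 21.1%. With 1 bp shared the shares were 90.2% and 47.0%, and with reciprocal overlap 24.1% and 18.1%. Against random placement inside genes the excess was 2.30-fold. The correlation between replicates across genes was 0.946, 0.850, 0.935, 0.956 and 0.947. The replicated list kept 77.8% of pooled peaks with −log10 q of at least 2. The cause of these shifts was not tested.

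The 7 lists called higher numbered 5 to 8 across alternatives. The 9 called lower numbered 1 with −log10 q of at least 5, 3 at 25% and 1 at 50% of the body, 4 without overlapping genes and 6 with peaks at or above the median enrichment, where fewer genes count, random lists hold fewer marked members and a list with 0 stands apart less. They numbered 8 to 9 with 1 replicate left out and 12 by mean coverage. Of single lists under single alternatives, 414 kept their call or lack of one, 37 lost the call and 12 gained one. Lists without a call, such as nephron progenitor, podocyte and stroma, fell on either side of their random lists depending on the alternative. The complex I list turned from higher to 0.845 times its random lists at 50% of the body, with no call there, and the Zfp call was lost there too. Calls held in 9 of 16 alternatives for the ureteric bud and endothelial lists, in 11 for brain neuron and striated muscle, in 12 for nerve and Schwann cell, in 13 for hepatocyte and mature proximal tubule and in 14 for the mature loop and distal list. The lists that gained calls were cilium (higher, in 2), adrenal and gonad (lower, in 2), histones (lower, in 3) and interferon (lower, in 5). Calls held in 16 of 16 for the ribosomal, proteasome, cell cycle, splicing, H3K36 and olfactory lists. These alternatives are not independent checks. Of the 6489 genes passing in replicate 1, 6471 passed in both, so the main calls are nearly those of replicate 1 alone. Leaving out replicate 2 thus nearly repeats the main setting, and equal peak numbers gave a similar count (6455 genes). Likewise, 10% in either replicate (8691 genes) nearly repeats replicate 2 alone (8673). A peak list shows nothing below its threshold, so depth limits every count of uncovered genes. No paired analysis was possible because there is a single group.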

Other observations

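The non-coding genes, all tests on X and that of last exon length were chosen after the pattern or result was seen. So were the tests of hardly marked cell type lists, both of their marked members' neighbours and of their other members. Long non-coding genes away from coding ones rarely carried the mark. Of 5176 long non-coding genes of at least 1 kb lying more than 5 kb from a protein-coding body, 19 were marked (0.367%, 95% Wilson interval 0.235 to 0.573), against 30.5% of protein-coding genes. The coding genes were not held to such a distance and lengths were not matched, so these shares come from unlike sets. The gene covered most was Mir17hg (chr14:115042879-115046727), the host of a microRNA cluster active in proliferating cells, at 76.3% in replicate 1 and 100% in replicate 2. Next came Snhg17, a host of small nucleolar RNAs, at a mean of 75.5%, Gm26930 at 68.4% and Malat1, an abundant nuclear RNA, at 52.5%. Gm26930 lies inside Gm26936 (chr1:137928389-137969240), another of the marked genes, and the marked A430106G13Rik overlaps Gm26936 too. The 19 genes are therefore not separate loci, and the Wilson interval does not allow for this. Of 34594 replicated regions, merged within 1 kb, 81 (0.234%) lay over 5 kb from every annotated gene, and the widest of these spanned 4.82 kb.

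The strongest peak of the replicated list by p lay on the 3' side of Hjurp, the chaperone of the centromeric histone (chr1:88262382-88270371), with a fold enrichment of 7.89. Next came zinc finger genes, Zfp146 (chr7:30160649-30163787) at 14.7 and Zfp157 (chr5:138454353-138459427) at 14.3. Of the 100 replicated peaks with the smallest p, 12 lay in genes named Zfp, against 1.97% of all replicated peaks.

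The excess of marked Zfp genes was set against 2 technical readings. Reads shared between clustered paralogs would raise clustered genes, yet 123 Zfp genes had no other gene named Zfp within 500 kb. They were marked 1.91 times as often as length-matched genes (76 against 39.7), and the 268 clustered ones 1.29 times. Neighbours under other symbols and reads shared between distant genes were not considered. The values thus bear only on sharing between neighbouring genes named Zfp. Overlap with other genes would end the excess once overlapping genes are left out, and it stood at 1.61 times. Within marked Zfp genes the last exon, which in such genes often encodes the finger array, was covered 34.7 percentage points more than the rest of the body as a median over 205 genes, against 20.2 (15.1 to 25.1) in length-matched lists and 18.4 (14.2 to 23.03) in lists matched on last exon length (one-sided permutation p = 0.0001, the smallest possible, for each). Matching on deciles of last exon length thus did not remove the excess on the last exon. Lengths within a decile may still differ, and last exon and body length were not matched together. No biological explanation was tested.

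Peaks of replicate 2 on X were found again in replicate 1 in 9.25% of cases, against 29.6% on autosomes. Lower fold enrichment or width of X peaks, GC content and all of these together were argued against as the whole cause. X peaks were found again 0.420, 0.318 and 0.432 times as often as autosomal peaks matched on them. No single autosome fell below 0.883. Among peaks with −log10 q of at least 10, matched on fold enrichment and width, the ratio was 0.555 (41 of 98 X peaks, lowest autosome 0.969). Peaks were not matched on p or q, and the median −log10 q was 2.97 on X against 4.25 on autosomes. Loss of X peaks that are weaker by p or q therefore stays open, also among the strong peaks. A candidate explanation, only if fold enrichment was computed against the control, which the sources leave open, is a higher control level on X in replicate 1: at the same p, fold enrichment on X relative to autosomes was 1.03 in replicate 1 and 1.11 in replicate 2, a ratio of 0.927 where single autosomes ran from 0.996 to 1.02. Whether that is large enough was not tested, and the share of males in each pool and the library batch stay open.

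In the lists of mature proximal tubule, erythroid, macrophage and leukocyte, and adrenal and gonad genes, 6 of 64 members were marked. These lists were picked after the list results were seen and by no fixed rule. The ureteric bud list, with 1 of 20 marked, was not among them. The mark of an overlapping or neighbouring gene is a candidate explanation for 5 of them, Star, Cd68, Cx3cr1, Fcer1g and Slc5a2. Of the 6 marked members 83.3% had another marked gene within 1 kb, against 8.62% of the 58 unmarked members (Fisher's exact test, two-sided, p = 0.000184). The same share among all marked genes was not computed. Marked genes may lie near other marked genes whatever the source of the mark, so this difference does not settle the source. In replicate 2, 99.3% of the covered bases of Cx3cr1 and 56.5% of those of Slc5a2 lay inside another coding gene, but 0% of those of Star, Cd68 and Fcer1g, where nearness is the only evidence. Cells of those types as the source stay open, since the other members' median coverage of 0% in replicate 2 is that of a set with the marked ones taken out. Tfrc, which dividing cells of many types use, had no such neighbour and stays open.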
